A study of Oryza sativa with 4 samples.

How the data were processed

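Leaf RNA of the rice cultivar Nipponbare was profiled by poly(A) RNA sequencing in 4 libraries. Nipponbare is the japonica cultivar on which the rice reference genome is based. Per the labels' protocols, total RNA was extracted with phenol and chloroform and lithium chloride, libraries were made with a strand-marking Illumina mRNA kit, and paired ends were read on a NovaSeq instrument. Per the submitters' processing notes, the processing involved FastQC 0.11.7, Trimmomatic, Bowtie2, RSEM and edgeR 3.26.3 and the genome build IRGSP-1.0. Their settings, the gene annotation and whether counting used the strand are not given in the sources used here.

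The deposited table holds expected counts per gene, per the file headers taken from RSEM's gene-level results, for 37858 gene IDs in 4 libraries, with no normalization. RSEM divides reads that match several genes among them, so its counts need not be whole. Between 4801 and 5569 IDs per library had a fractional count. Genes with fractional counts share reads with other copies, and their values are uncertain to that extent. The table had 0 columns of other samples. Samples were grouped by their titles, as control 1 and 2 and heated 1 and 2. The treatment label of control 2 gives 30 °C, as for both heated libraries, whereas control 1 has 25 °C. The labels do not say whether this is an entry error. Grouping by this label instead was run as an alternative. Nothing in the labels says whether replicates came from separate plants, so the p-values measure only the spread between these libraries.

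The file does not pair its IDs with gene names, and the reference table at hand (assembly ASM3414082v1) matched 1 of the 37858 IDs. The 23 gene lists and 28 product families chosen before the data were examined needed such names. None of the 309 listed IDs was named in the reference table (0 matched), so no list or family was tested and no gene is given a name or function. IDs starting with Os follow the rice locus naming, in which the digits after Os give the chromosome and the last digits follow the order of genes along it. No coordinates were used.

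From the deposited expected counts, rounded to whole numbers, differential expression was computed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on all 4 libraries, with group as the only term. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 22184 IDs. Library sizes were scaled by TMM. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Counts relative to the scaled library size (CPM) were computed from the same sizes. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Where both libraries of a group were at 0, the fold is a lower bound computed against a floor of 3 counts over the group. Intervals and floors cover counting error only.

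The test was checked on simulated counts with 200 changed genes, drawn from the real means and library sizes. With gene-wise dispersions it recovered 32% of genes changed 2-fold and 77% of genes changed 4-fold. Of the calls in these runs, 22.9% and 18.5% were genes that had not been changed. With dispersions on the fitted trend, 35% and 83.5% were recovered, and 9.09% and 5.65% of calls were false. The share of false calls was thus above the nominal 0.05 in every run, and further above it with gene-wise dispersions. No setting was repeated, so 5.65% cannot be told apart from the nominal 0.05.

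The rule for named genes, fixed before the data were examined, took the genes with the largest fold changes in each direction among called genes whose groups did not overlap and whose mean was at least 1 CPM. Because the IDs have no names here, only the first 2 of each direction are printed. The replicate numbers were not taken to pair libraries. Alternatives covered the scaling, the filter, DESeq2 1.42.0, edgeR's exact test, limma 3.58.1 with voom, a fold threshold, a replicate block, grouping by the treatment label and leaving out each library. Summing rows with identical counts, a robust fit and unrounded counts were added after seeing the data. For the position of one control between the other control and the heated libraries, genes were called by the same edgeR test without the control to be placed, and positions were taken on log2(CPM + 0.5).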

Results

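Leaves of the progeny of rice seeds given a heat treatment were compared with leaves of control progeny, with 2 libraries in each group. Total expected counts were 15444235 and 17214538 in control 1 and 2, and 17298384 and 16605260 in heated 1 and 2. Between 26366 and 27436 gene IDs had a count above 0 in a library. The 10 most abundant genes took 8.51% of the counts in control 1 and between 6.18% and 6.65% in the other libraries.

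The first question was which genes differed in progeny leaves after heat treatment of the seed. Of the 22184 genes tested, 155 were called, of which 55 were higher and 100 were lower in the heated group (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 2 libraries per group). Genes called higher were mostly scarce in control leaves. Their median level was 2.43 CPM in control and 16.3 CPM in heated leaves, and their median log2 fold change was 3.02. Genes called lower were well expressed in control leaves, with a median of 51.6 CPM against 14.6 CPM in heated leaves and a median log2 fold change of -1.84. Among the genes called higher, 33 changed at least 4-fold, and among those called lower 44 did. The smallest called change was 1.01 on the log2 scale. The median log2 fold change of all tested genes was 0.0061.

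**Figure D1:**
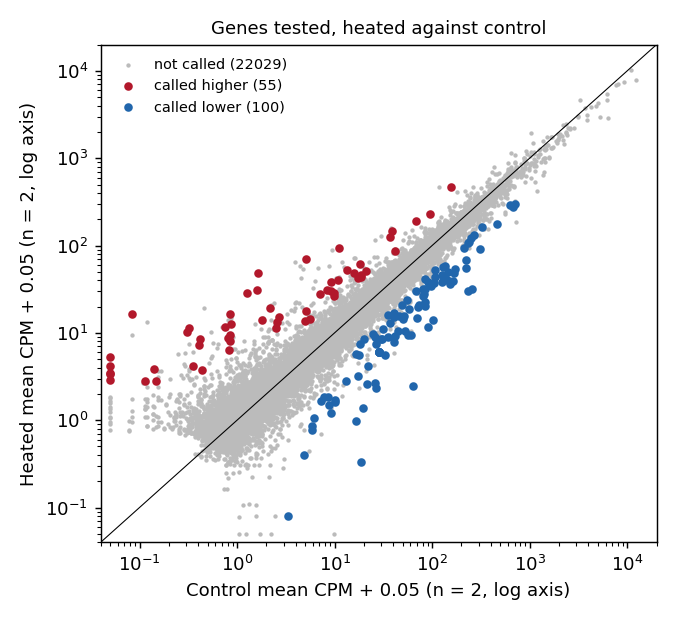
Mean level of each tested gene in control (x axis) and heated (y axis) leaves, in CPM plus 0.05 on log axes, with 2 libraries per group. Red points are the 55 genes called higher in heated leaves, blue points the 100 called lower, grey points the genes not called, and the line marks equal levels.

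Among called genes with a mean of at least 1 CPM, Os02g0191650 had the largest fitted increase, a log2 fold change of 9.47. It was listed at 0 in both control libraries, so this value depends on the fit and its rank is not settled. In the heated libraries it had 5.15 and 5.46 CPM, a mean of 5.30 ± 0.213 CPM (SD, n = 2). This is at least 56.4-fold higher in heated leaves, with an edgeR adjusted p of 0.0201. Its counts of 91.86 and 92.21 were fractional, so some of its reads also matched other genes. Os07g0218200 was likewise listed at 0 in both controls and reached 4.13 ± 0.975 CPM (SD, n = 2) in heated leaves, at least 43.9-fold higher (edgeR adjusted p = 0.0294). In all, 5 of the genes called higher were at 0 in both controls, and 22 had a control mean under 1 CPM.

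Os01g0644500 had the largest fitted decrease. It had 50 and 54 counts in the controls and expected counts of 0.26 and 0.65 in the heated libraries. On rounded counts, 104 against 1, the control level was 113-fold that of heated leaves (exact 95% counting interval 19.9 to 4514), and the edgeR adjusted p was 0.0294. The preceding tested ID moved the opposite way, from 0 in both controls to expected counts of 46.74 and 50.35. The sum of the pair was 50, 54, 47 and 51 counts in control 1, control 2, heated 1 and heated 2. The fractional heated counts of both IDs thus summed to whole numbers, so some reads there were divided between these IDs. Os02g0677300 fell from 18.6 ± 5.21 CPM in control to 0.285 ± 0.151 CPM in heated leaves (SD, n = 2). Its log2 fold change was -5.98 (SE 0.42) with an edgeR adjusted p of 0.0116. On counts, its control level was 65.6-fold that of heated leaves (exact 95% counting interval 35.4 to 138). This interval lies within that of Os01g0644500, so the order of these genes is not settled. Among the 100 genes called lower, 6 had a heated mean under 1 CPM, and 0 were at 0 in both heated libraries.

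Of the genes called lower, 6 IDs close together on chromosome 2 held the same 4 expected counts. Each had 438.33 and 460.67 in the controls and 124.33 and 85.83 in the heated libraries, so their log2 fold change of -2.23 (edgeR adjusted p = 0.0192) was counted once per copy. Over the whole table, 102 IDs with a total of at least 40 counts fell into 47 such sets of identical rows. With each set taken once, the called genes numbered 150, of which 95 were lower.

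All 155 called genes had both heated libraries on the same side of both controls. This was the case for 40.5% of all tested genes, where chance gives 33.3% with 2 against 2. An unadjusted p under 0.05 was found for 2047 genes, or 9.23% of those tested. The count depended on the setting: on the same genes edgeR's exact test called 732 (394 higher, 338 lower), the DESeq2 Wald test, with its own filter and 23456 genes, called 551 (276 higher, 275 lower), and the count was 504 without control 1, 2506 without control 2, 64 without heated 1 and 129 without heated 2 (86 higher, 43 lower). In simulated data with gene-wise dispersions, between 18.5% and 22.9% of the calls were genes that had not been changed. With dispersions on the fitted trend these shares were 5.65% and 9.09%.

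The second question was whether the libraries of each group were alike, because the treatment label of control 2 gives the temperature of the heated group. Control 1 and control 2 differed by at least 2-fold in 2010 of the 22184 genes, and heated 1 and heated 2 in 869. The common biological coefficient of variation was 24.6% in the control pair and 13.3% in the heated pair. Control 2 had 1491 genes at least 2-fold apart from heated 2 and 1519 from heated 1, fewer than from control 1. Control 1 had 2574 genes as far apart from heated 2 and 2852 from heated 1, more than from control 2. Across genes, the Pearson correlation of log2 CPM was 0.959 between the controls and 0.979 between the heated libraries. It was 0.965 between control 2 and heated 2 and 0.959 between control 2 and heated 1. Control 1 had 0.950 with heated 2 and 0.945 with heated 1. Genes are not independent replicates. On the first principal component, with 54.7% of the variance, control 1 scored -69.4, control 2 -11.5, heated 1 45.4 and heated 2 35.5.

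**Figure D2:**
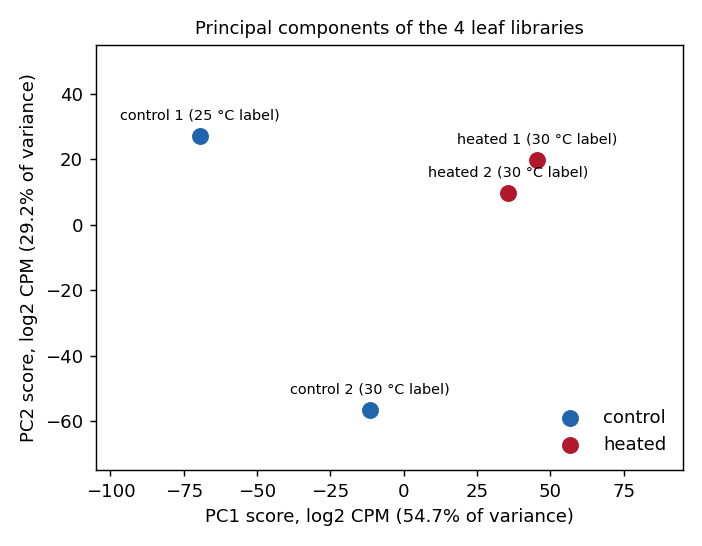
Scores of the 4 libraries on the first (x axis, 54.7% of variance) and second (y axis, 29.2%) principal component of log2 CPM over 22184 genes, 1 point per library, with the temperature in its treatment label. Control 2 lies between control 1 and the heated libraries on the first component and apart from the other 3 on the second.

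Grouping by the treatment label set control 1 (25 °C) against the other 3 libraries (30 °C). This called 174 genes, 135 higher and 39 lower at 30 °C, by the edgeR quasi-likelihood test, in which the lone library was assumed to vary like the other 3. An unadjusted p under 0.05 was found for 4950 of 23285 genes. If the label of control 2 is an entry error, this comparison sets control 1 alone against the rest. Of these, 0 were among the 155 genes called by title. The groupings place control 2 on opposite sides, so few genes could pass both tests, and the overlap carries no further information.

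Without control 2, control 1 differed from the heated libraries in 2506 genes. In the 2488 of these that were also tested with all libraries, control 2 lay at a median position of 0.74 (quartiles 0.40 and 0.98) on a log2 scale from control 1 at 0 to the heated mean at 1. It was nearer to heated in 69.2% of these genes. In simulated libraries with alike controls this median was 0.15, over 871 genes. The simulation gave both controls the same spread. Without control 1, control 2 differed from the heated libraries in 504 genes. In 498 of these, control 1 lay at a median of 0.13 (quartiles -0.087 and 0.37) and was nearer to control 2 in 84.3%. The simulation gave a median of 0.15 there, over 900 genes. All 155 called genes were also called without control 1 and without control 2. With 1 control left, the spread came from the heated pair, the less variable of the 2 pairs (13.3% against 24.6%), so deviations of that control alone count as differences and 2506 and 504 are no counts of heat effects.

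**Figure D3:**
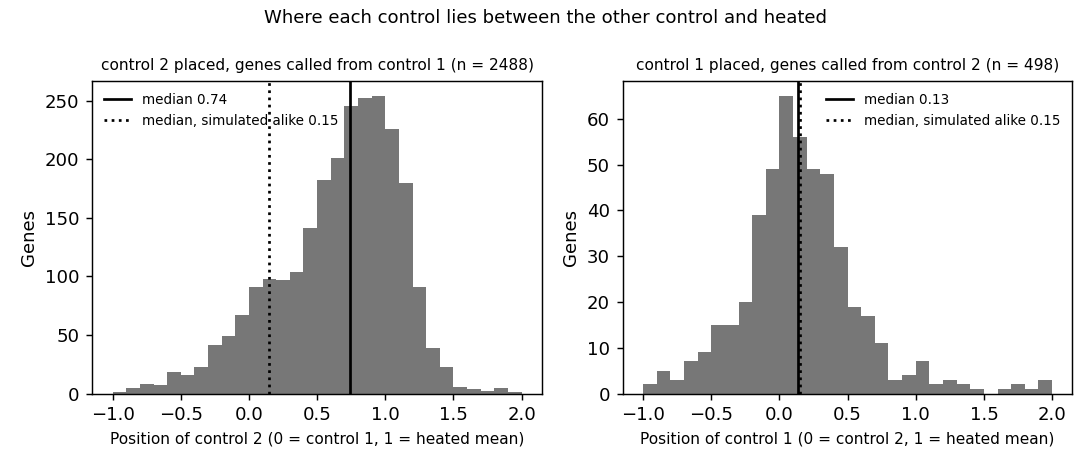
Histograms of the position of control 2 (left, 2488 genes called between control 1 and heated) and of control 1 (right, 498 genes called between control 2 and heated), where 0 is the level of the other control and 1 the heated mean on a log2 scale; the y axis counts genes, and 11 and 8 genes lie outside the range drawn. Solid lines mark the medians of 0.74 and 0.13, dotted lines the median of 0.15 in simulated libraries with alike controls (871 genes left, 900 genes right).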

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

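The count of 155 called genes (55 higher, 100 lower) stayed within 1.5 times under the other scalings, the stricter filter, limma-voom and the added settings. The fold threshold, a log2 fold change of at least 1 in the same fit, could not change the count, because the smallest called change was 1.01. DESeq2's size factors moved the median log2 fold change of all genes by -0.0093 and upper-quartile factors by -0.0085. Without a filter on low counts 419 genes were called (215 higher, 204 lower), with DESeq2's Wald test and filter 551 (276 higher, 275 lower) and with edgeR's exact test 732 (394 higher, 338 lower). In these settings the genes called higher were 51.3%, 50.1% and 53.8% of the calls, against 35.5% in the reported test, and each kept all 155 genes. With a replicate block 532 genes were called (295 higher, 237 lower). The labels do not say whether equal replicate numbers mark a shared batch. The difference between replicates 1 and 2 had a correlation of 0.0039 across genes between control and heated. This gives no sign of a shared batch but does not exclude one. Grouping by the treatment label called 135 genes higher and 39 lower, with 0 shared with the reported calls; the groupings place control 2 on opposite sides. Leaving out 1 library gave between 64 and 2506 calls, with 24 to 1307 higher and 40 to 1199 lower. The count was 504 without control 1 and 2506 without control 2, each with all 155 reported genes. It was 64 without heated 1, with 52 of the reported genes, and 129 without heated 2 (86 higher, 43 lower), with 70 of them. A group left with 1 library was assumed to vary like the other. Except for the grouping by treatment label, 33 genes were called in every setting. The stricter filter (10 counts in every library) dropped all 4 named genes. Of 64 results for these genes under an alternative, 58 stayed called in the same direction, including those under the fold threshold, which could not fail. Another 6 did not pass and 0 reversed. These 6 were all 4 genes under the treatment-label grouping, and Os07g0218200 (adjusted p = 0.0626) and Os01g0644500 (adjusted p = 0.0648) without heated 1 in edgeR. The cause of these shifts was not tested. The alternatives planned for the gene lists were not run, because no list could be named. With 2 libraries per group, the simulation recovered 32% of 2-fold changes, so most changes of that size are below what this design detects.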

Other observations

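The tests below on control 2 as a heated library, on the treatment label, on the pair of opposite genes and on other splits of the libraries and the simulated libraries were chosen after the result was seen, as were the counts of genes at 0, by chromosome and of neighbours.

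Both controls were at 0 and both heated libraries had at least 10 counts in 18 IDs, and the opposite held in 6. The other ways to split the 4 libraries into pairs gave 10 and 9 such IDs, and 10 and 4, and the difference was not tested. Genes called higher in heated leaves were over-represented on chromosome 12, where 10 of the 55 lay (18.2%, against 5.62% of tested genes; Fisher's exact test, two-sided, p = 0.000872, adjusted p = 0.0209 over 24 tests). This excess did not hold under several alternatives: it was 20 of 276 genes (p = 0.235) with DESeq2, 4 of 42 (p = 0.294) with at least 10 counts in every library, 19 of 248 (p = 0.165) without control 1 and 3 of 24 (p = 0.149) without heated 1, all by Fisher's exact test. It was the only 1 of 24 tests under an adjusted p of 0.05. These tests treat genes as independent, whereas called genes tended to lie next to each other, as given below.

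Called genes also tended to lie next to each other. With identical rows taken once, 9 pairs of called genes were adjacent in ID order among the tested genes, against a mean of 1.01 when calls were permuted within 10 bins of expression (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). In 7 pairs both genes moved the same way and in 2 they moved oppositely. Of these 2, only the pair that holds Os01g0644500 was examined further. The excess was not confined to genes with fractional counts. Among genes with whole counts in every library, 5 pairs were adjacent, 4 of them among the 9, against a permuted mean of 0.807 (one-sided permutation p = 0.00135). A whole count does not show that a gene shared no reads, so reads shared between near-identical copies are not excluded as a source. The excess also held without each library in turn, with 39, 355, 4 and 7 pairs without control 1, control 2, heated 1 and heated 2, against permuted means of 10.8, 274, 0.153 and 0.665. Those lists came from subsets of the same libraries and shared many genes with the reported calls, so they are no separate support. Overlapping genes and local co-regulation stay open, since no coordinates were used.

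The opposite pair that holds Os01g0644500 may be a change in where reads were counted and not in how much was transcribed. The summed level of the pair was 3.27 ± 0.225 CPM in control and 2.83 ± 0.277 CPM in heated leaves (SD, n = 2), a log2 ratio of -0.21, while the fitted log2 fold change of Os01g0644500 alone was -6.49. This is consistent with the same reads being counted under one ID in control and under its neighbour in heated leaves. In the heated libraries the fractional counts of the IDs (46.74 with 0.26, and 50.35 with 0.65) summed to whole numbers. Some reads there thus matched both IDs and were divided between them by RSEM. Whether this division, a sequence difference or another transcript form made the switch was not tested, and the reads were not used here.

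Control 2 lay between control 1 and the heated libraries on the first principal component and, by its median position of 0.74, in the 2488 genes separating them, but apart from the other 3 on the second component. That control 2 is a heated library under a control title is argued against. In the 498 genes separating control 2 from heated, control 1 was nearer to control 2 in 84.3%. Unlike the heated libraries, control 1 had no part in the choice of these genes. Simulated alike controls gave 81.9%, and 20 simulations of control 2 as a heated library gave 40% to 66.7%, with 2 to 90 genes each. The simulations drew genes independently. The exact 95% binomial interval over genes, 80.8% to 87.4%, also treats genes as independent, which they are not, and does not cover spread between libraries. A further check took 354 abundant genes (mean of at least 20 CPM) called without control 2 and changed at least 2-fold between control 1 and heated. Control 2 was under 10% of the way to heated in 20.6% of them and over 90% of the way in 27.4%. Here the way was measured on CPM and not on the log2 scale of the positions. A mixture of control 1 and heated material in 1 share is argued against as the whole source. The bound set beforehand was over 10% in both ranges, and both values passed it. Of 9 simulated mixtures, with shares of 10% to 90% and the fitted spread of each gene, none passed 7.25% in both ranges. These runs held 510 to 568 such genes each and took the levels of control 1 as those of control material. Deviations of control 1 alone could put further genes over 90%, so a mixture together with such deviations stays open. Exact 95% binomial intervals over genes had lower ends of 16.5% and 22.8%, but they too treat genes as independent. It stays open whether the 174 genes called between control 1 and the rest follow its 25 °C label or that library alone, which cannot be told apart, because 1 library has this label, and whether the 30 °C label of control 2 is an entry error.

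Of the 3 ways to split the 4 libraries into pairs, 1, the real one, called as many as 155 genes, and the highest other called 0. With 3 splits no share under 0.05 is possible. Each other split put 1 control and 1 heated library in each pair, so the difference between the groups entered the spread. This favours 0 calls there by design, so 155 against 0 is no support for the grouping.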
